A study of Acyrthosiphon pisum with 15 samples.

How the data were processed

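RNA was measured by sequencing of whole bodies of the pea aphid, Acyrthosiphon pisum, a sap-feeding insect whose adults take several forms, or morphs. Per the labels, 15 libraries were made, from 5 morphs in each of 3 clones named F1, I18 and BK11, with 30 adult aphids in each. The labels call the clones biological replicates, so every spread and p-value here measures the differences among clones together with those among preparations. Per the labels, asexual females were kept with 16 h of light and 8 h of dark at 18 °C, and sexual females and males with 13 h of light and 11 h of dark at 15 °C. Adults were 2 days old in every group except the sexual females, which were 2 to 6 days old. Rearing conditions therefore cannot be separated from morph where asexual females were compared with the other morphs. Nor can the age range where sexual females were compared with any other morph. No sequencing batch is given in the labels.

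Per the labels, RNA was extracted with phenol and chloroform, libraries carried sample-specific tags, and sequencing was done on an Illumina sequencer. The deposited signal is a gene count divided by a size factor of its library, given for 20657 gene models and not scaled for gene length. DESeq2 is named in the submitters' processing notes, without a version. The read aligner, the counting tool, the strand setting, the genome build and the annotation release are not given in the sources used here. In each library, 100% of the deposited values were whole multiples of its smallest positive value within a tolerance of 0.001 of a read, so the whole read counts could be recovered. DESeq2 size factors recomputed from the recovered reads matched the deposited scaling, with a product of recomputed factor and value per read of 1 in every library. Recovered totals ran from 28721904 to 75066116 reads per library. A count of 3 reads, taken as the limit that a count of 0 allows, corresponded to normalised counts of 1.63 to 5.95 depending on the library. Such limits, and the counting interval given for a gene with few reads, cover counting error only.

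Tests were run on log2(value + 1) with limma 3.58.1 in R 4.3.3, using a mean-dependent prior variance. All 15 libraries entered one fit with 5 morph means and 10 residual degrees of freedom. Gene models with a normalised count of at least 10 in at least 3 libraries were tested, which kept 20301 and left out 356. P-values were adjusted by Benjamini and Hochberg within each of 6 comparisons, at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes near 0. Errors of fold changes are standard errors, and errors of normalised counts are standard deviations over 3 clones. The differences among morphs and among clones were tested with limma F tests, the second in a fit that held both terms. Principal components were computed on the same log values with genes centred.

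The comparisons, tests, gene choice and most alternatives were fixed before the data were examined. The planned choice of 5 named genes in each direction needed gene names. Of the 20657 identifiers, 61 were found in the gene table of assembly pea_aphid_22Mar2018_4r6ur_v2, used here for names alone, and 1 of them carried a gene symbol, Syt4. After the identifiers were seen, the rule was therefore reduced to 2 identifiers in each direction per comparison. They had the largest fold change among those past the threshold with a mean normalised count of at least 100 over all libraries and the same direction in all 3 clones. Syt4 was added in every comparison because it was the only identifier with a symbol. For the clones, the 2 gene models with the smallest p at that mean were taken. The 27 planned gene lists were defined by product names, and neither these tests nor the planned test for the X chromosome was run, since the identifiers could not be paired with names or positions.

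Because each clone supplied a library to every morph, samples were paired by clone. Deviations of libraries from their morph mean correlated, across genes, between libraries of the same clone, with r from 0.135 for a sexual female and wingless male pair to 0.642 for a winged and wingless asexual female pair. The fit with clone as a block was run beside the one without it. The other alternatives fixed beforehand were pseudocounts of 0.5 and 8, no filter or a filter of 50, trimmed mean (TMM) scaling, robust prior variances, a fit of only the groups compared, and leaving out each library or each clone. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as 2 more of them. Sample quality weights, the block without the I18 wingless male library, and a fit without 4 libraries whose values raised doubt were chosen after seeing the data. Those 4 were the I18 wingless male, the BK11 winged male, the BK11 wingless male and the BK11 sexual female.

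Trimmed mean scaling moved the log2 scale by 0.14 for winged against wingless asexual females. The shift was −0.15 for the difference between the wing effects, −0.12 for sexual against wingless asexual females and −0.10 for males against asexual females. It was less than 0.1 in size for the other comparisons. The pseudocount was added after scaling, so fold changes of gene models near 0 moved by less than the shift. No pair of libraries within a morph agreed within sampling noise, so each library was counted once.

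The fits were tested on simulated data, with counts for 20301 gene models drawn at the real depths and 50 gene models changed at each fold. Each gene model had its mean over all 15 libraries in every morph, apart from the changes placed. The simulated lists held 52 to 130 calls, against 71 to 11936 in the real data. Adjusted p-values depend on the length of the list, so these rates do not give the recovery in the real fits. For winged against wingless asexual females, 20% of the 4-fold and 80% of the 64-fold changes were recovered with 3 false calls. The corresponding values were 30%, 76% and 7 for winged against wingless males, and 14%, 56% and 2 for the difference between the wing effects. They were 26%, 76% and 6 for wingless males against sexual females, 18%, 68% and 3 for sexual against wingless asexual females, and 48%, 98% and 10 for males against asexual females. Figures were drawn with matplotlib.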

Results

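Whole-body transcriptomes were compared among 5 adult morphs of the pea aphid. Asexual females bear live young without mating and occur as winged and wingless forms. Sexual females lay eggs after mating and are wingless, and males occur as winged and wingless forms. Each morph was sampled once in each of the clones F1, I18 and BK11, giving n = 3 per morph and 15 libraries. Recovered reads per library ranged from 43309865 to 75066116 in winged asexual females and from 28721904 to 69726381 in wingless asexual females. They ranged from 52222811 to 73961669 in sexual females, 29233690 to 33003478 in winged males and 31918756 to 42784904 in wingless males. The sum of normalised counts was 38300000 ± 2350000 (SD, n = 3) in winged asexual females and 62300000 ± 5140000 in wingless asexual females. It was 47500000 ± 1330000 in sexual females, 41200000 ± 2320000 in winged males and 41900000 ± 1850000 in wingless males. The 10 most abundant gene models held 16.2% of the normalised counts in the I18 sexual female, 14.6% in the BK11 sexual female and 6.41% in the F1 sexual female.

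Sex and reproductive mode separated the libraries far more than wings or clone did. The first principal component held 46.7% of the variance and parted the 6 male libraries, at scores of 167.5 to 243.6, from the 9 female libraries, at −188.9 to −96.89. The second held 22.8% and parted sexual females, at 172.0 to 240.3, from asexual females, at −139.6 to −65.74. Of the 20301 gene models tested, 15134 (74.5%) differed among the 5 morphs by the limma F test at an adjusted p threshold of 0.05. The 3 clones differed in 1431 gene models (7.05%) once morph was accounted for. That number was 394 without clone F1, 836 without I18, 595 without BK11 and 820 without 4 doubted libraries, the I18 wingless male, the BK11 winged male, the BK11 wingless male and the BK11 sexual female. Among the clone differences, ACYPI081660-RA stood at a normalised count of 12.01 ± 6.71 over the 5 libraries of F1, against 5061 ± 1499 in I18 and 4343 ± 972.5 in BK11 (limma adjusted p = 1.6e-08). ACYPI073515-RA was also lowest in F1, with 94.8 ± 43.5 in F1, 7832 ± 4615 in I18 and 11220 ± 5853 in BK11 (limma adjusted p = 1.6e-08). Without clone F1 the limma adjusted p was 0.716 for ACYPI081660-RA and 0.16 for ACYPI073515-RA.

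**Figure D1:**
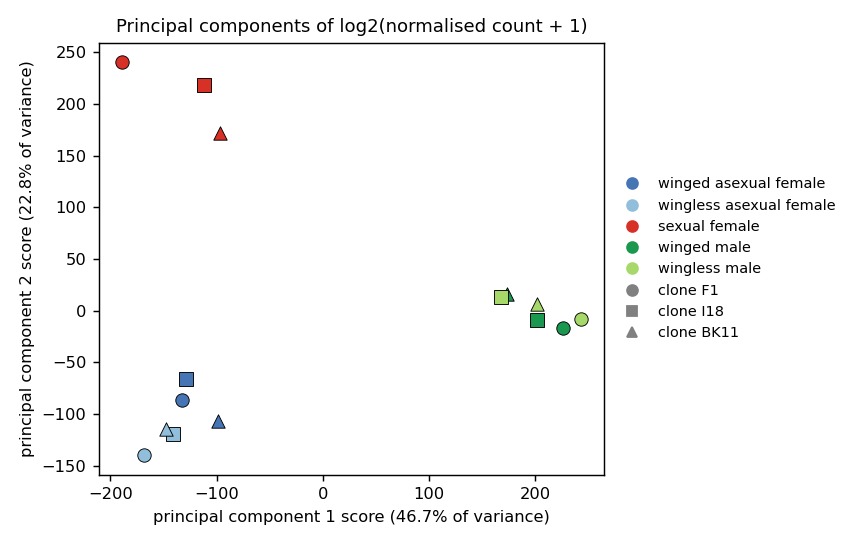
Scores of the 15 libraries on the first (x axis) and second (y axis) principal components of log2(normalised count + 1), with colour for the morph and symbol shape for the clone. The 6 male libraries lie at 167.5 or above on the first axis and the 3 sexual female libraries at 172.0 or above on the second.

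Winged and wingless asexual females, which arise from one genotype by environmental induction, were compared to ask which genes go with wings in females. In winged females 922 gene models were higher and 1384 lower, together 11.4% of those tested (limma, adjusted p threshold 0.05). All 922 and all 1384 moved the same way within each of the 3 clones. Most of these differences were moderate, with a median log2 fold change of 1.62 among the higher and −1.30 among the lower gene models. An 8-fold difference or more was reached by 112 higher and 87 lower gene models, and a 32-fold difference by 4 and 21. The lower gene models were the more abundant ones over all 15 libraries, males and sexual females included, with a median normalised count of 3442 against 763 for the higher ones. ACYPI061655-RA had the largest increase among the gene models that met the naming rule, from 22.8 ± 11.5 in wingless to 1406 ± 835.4 in winged females (log2 fold change 5.83 ± 1.17, limma adjusted p = 0.0071). ACYPI081067-RA increased from 17.3 ± 22.9 to 348.1 ± 83.3 (5.13 ± 1.10, limma adjusted p = 0.0099). ACYPI086947-RA was lower in winged females, at 12.8 ± 15.0 against 1366 ± 744.7 (−7.50 ± 1.67, limma adjusted p = 0.012). ACYPI080518-RA was also lower, at 150.2 ± 236.0 against 7164 ± 3543 (−7.14 ± 1.60, limma adjusted p = 0.012). Of 22 alternatives, the call was lost in 2 for ACYPI061655-RA, 3 for ACYPI081067-RA, 4 for ACYPI086947-RA and 5 for ACYPI080518-RA. Syt4 (ACYPI009209-RA), whose symbol stands for synaptotagmin 4, a protein of vesicle membranes, was higher in winged females, at 2906 ± 944.7 against 1021 ± 364.6 (1.51 ± 0.34, limma adjusted p = 0.012), and this call was lost in 7 of 22 alternatives, with adjusted p from 6.9e-05 to 0.175.

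Higher gene models made up 40.0% of the female wing calls with the deposited scaling, 53.0% with trimmed mean scaling, 54.4% with edgeR and 45.6% with DESeq2, so the majority of lower calls was not kept under every scaling. Leaving out the winged F1, winged I18, wingless F1 or wingless BK11 library reduced the calls to 320, 434, 397 and 420 higher and to 737, 747, 669 and 747 lower, and leaving out clone F1, I18 or BK11 reduced them to 39, 160 and 117 higher and to 132, 558 and 297 lower.

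**Figure D2:**
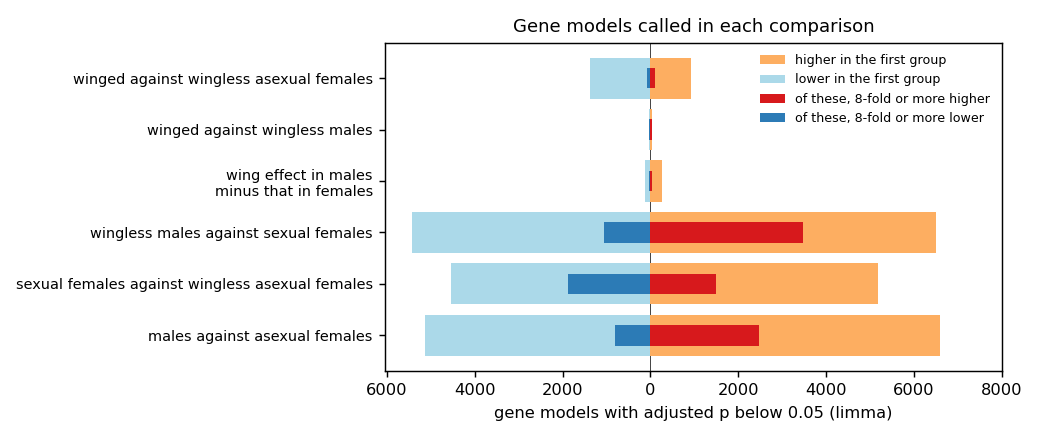
Number of gene models with a limma adjusted p below 0.05 in each of the 6 comparisons (x axis, counts to the right for higher and to the left for lower in the first-named group), with narrow bars for differences of 8-fold or more. The 3 comparisons across sex or reproductive mode called 9725 to 11936 gene models, and the wing comparisons 2306 in asexual females and 71 in males.

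In males, where winged and wingless forms are set by genotype at a sex-linked locus, the same question gave far fewer calls. Wings cannot be separated here from other genetic differences linked to that locus. Winged males had 35 gene models higher and 36 lower than wingless males (limma, adjusted p threshold 0.05). The differences called were large, with a median log2 fold change of 4.02 among the higher and −4.89 among the lower gene models, and 24 higher and 35 lower ones reached 8-fold. A shorter list needs smaller unadjusted p-values to pass the threshold, so these medians cannot be compared with those of the female calls. ACYPI004305-RA was at 8519 ± 6420 in winged and 48.0 ± 27.4 in wingless males (log2 fold change 7.18 ± 1.14, limma adjusted p = 0.018). ACYPI080808-RA was at 31060 ± 24490 in winged and 176.2 ± 86.9 in wingless males (6.84 ± 1.24, limma adjusted p = 0.034), and at a mean of 0 in winged asexual females. On the other side, ACYPI31637-RA was at 2.17 ± 1.97 in winged and 764.2 ± 910.8 in wingless males (−6.85 ± 1.13, limma adjusted p = 0.023). ACYPI000982-RA was at 10.4 ± 8.04 in winged and 841.4 ± 875.0 in wingless males (−5.94 ± 0.92, limma adjusted p = 0.016). The highest of the wingless male values lay in the I18 library for both, at 1784 for ACYPI31637-RA and 1819 for ACYPI000982-RA. Under alternatives the call was lost in 10 of 22 for ACYPI004305-RA, 12 of 22 for ACYPI080808-RA, 4 of 13 for ACYPI31637-RA and 9 of 22 for ACYPI000982-RA. In the alternatives not counted for ACYPI31637-RA it fell below the filter. These include every fit without a wingless male library or a clone, so its share cannot be compared with the others. Syt4 (ACYPI009209-RA) showed no call, at 8136 ± 2415 in winged and 6503 ± 1799 in wingless males (0.32 ± 0.34, limma adjusted p = 0.98).

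The male wing calls depended on single libraries and on the tool: edgeR called 6 higher and 1 lower, DESeq2 122 and 501, the limma fit of the 6 male libraries alone 3 and 0 (1158 at an unadjusted p under 0.05), and the fit with clone as a block 49 and 79, which held all 71 of the calls. With no difference, a share of 0.05 of the 20301 gene models would be expected at that unadjusted level, and 1158 lies little above it. The unadjusted count in the next sentence lies below it. Leaving out the winged F1, winged I18 or winged BK11 library gave 32, 10 and 13 higher and 82, 12 and 7 lower, leaving out the wingless F1, I18 or BK11 library gave 18, 16 and 40 higher and 3, 3 and 214 lower (21 higher and 8 lower without I18 if the filter of the full set is kept), and without the 4 doubted libraries 1 was higher and 0 lower, with 763 at an unadjusted limma p under 0.05.

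The wing differences of the sexes were then compared gene by gene. Of the gene models called in both sexes, 5 were higher in winged insects of both and 2 lower in both, against 1.59 and 2.45 for independent lists of these sizes, and 2 had opposite directions. The lists shared each gene model's estimate of spread from the same fit, so they are not independent even without shared effects. Those higher in both were ACYPI27568-RA, ACYPI004530-RA, ACYPI005193-RA, ACYPI006477-RA and ACYPI22539-RA, named after their values were seen. The largest of these, ACYPI27568-RA, had a log2 fold change of 2.17 ± 0.58 in females and 4.01 ± 0.58 in males (limma adjusted p = 0.029 and 0.011). ACYPI008635-RA was lower in winged insects of both sexes, with −3.27 ± 0.52 in females and −4.11 ± 0.52 in males (limma adjusted p = 0.0021 and 0.0058). ACYPI009505-RA was the other, with −2.38 ± 0.40 and −2.40 ± 0.40 (limma adjusted p = 0.0025 and 0.022). With clone as a block 5 were higher and 6 lower in both, and without the 4 doubted libraries, or without clone F1, I18 or BK11, 0 were called in either direction. Leaving out the winged F1, wingless F1 or wingless BK11 asexual female library gave 0 higher and 2 lower, and the other single libraries 2 to 6 higher and 1 to 4 lower. Across all gene models, which are not independent replicates, the log2 fold changes of the sexes had a Pearson correlation of 0.12. The gene models higher in winged females had a median log2 fold change of 0.06 in males, and those lower had −0.10.

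**Figure D3:**
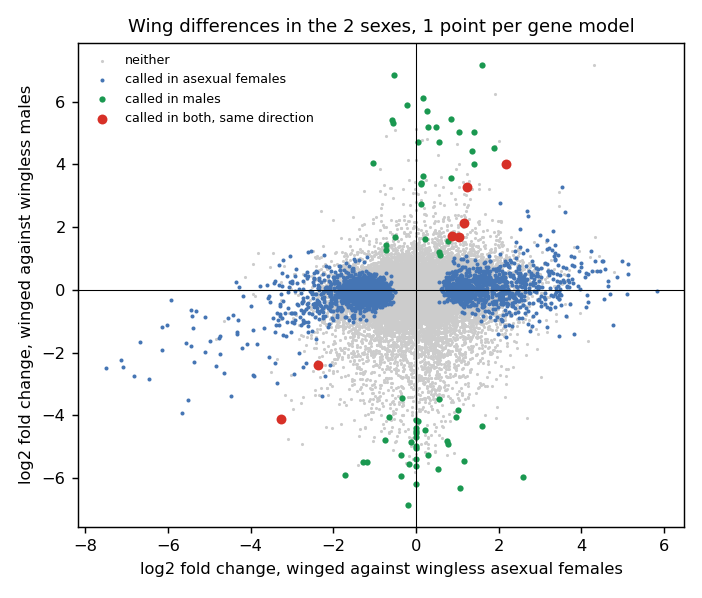
Log2 fold change of winged against wingless asexual females (x axis) and of winged against wingless males (y axis), with 1 point per gene model tested. Red points mark the 5 gene models higher and the 2 lower in winged insects of both sexes, and 94.8% of the 2306 gene models called in females lie within 1 of 0 on the male axis.

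The difference between the wing effects, male minus female, was tested directly. It was positive for 260 and negative for 120 gene models (limma, adjusted p threshold 0.05). The wing effect was larger in females for 335 of these 380 and larger in males for 45, and the gene models named next, chosen for the size of the difference, are among the 45. ACYPI065920-RA, at 535.6 ± 463.6 in winged and 6.56 ± 4.68 in wingless males, was near 70 in both asexual female morphs, with a difference of effects of 5.95 ± 1.18 (limma adjusted p = 0.028). ACYPI41054-RA was at 534.6 ± 446.2 in winged and 12.6 ± 11.9 in wingless males, with a difference of 6.09 ± 1.44 (limma adjusted p = 0.049), and whether both models share reads was not tested. ACYPI001157-RA was at 883.7 ± 1124 in wingless and 25.9 ± 9.48 in winged males, and at 0.60 ± 1.04 in wingless and 13.1 ± 14.1 in winged females (−6.77 ± 1.49, limma adjusted p = 0.041), and its wing effect was called in neither sex (limma adjusted p = 0.17 in males and 0.12 in females). ACYPI46674-RA was at 657.1 ± 773.3 in wingless and 7.86 ± 4.59 in winged males and at 0 in all wingless asexual females (−6.63 ± 1.29, limma adjusted p = 0.027). The I18 library was the highest of the wingless males for ACYPI001157-RA, at 2171, and ACYPI46674-RA, at 1534, and without it the limma adjusted p was 0.057 and 0.034. The I18 library was also the highest of the winged males for ACYPI065920-RA, at 1071, and ACYPI41054-RA, at 1043, and without it the limma adjusted p was 0.075 and 0.13. The difference for Syt4 (ACYPI009209-RA) was −1.18 ± 0.48 and missed the threshold (limma adjusted p = 0.23).

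Positive differences made up 68.4% of these calls with the deposited scaling, 52.3% with trimmed mean scaling, 50.8% with edgeR and 49.2% with DESeq2. No gene model was called by limma without the 4 doubted libraries (2343 at an unadjusted p under 0.05) or without clone F1, I18 or BK11 (1985, 1994 and 2752), and leaving out any 1 of the 12 libraries moved the positive calls to between 26 and 473 and the negative ones to between 12 and 275. The call of ACYPI41054-RA was lost in 17 of 28 alternatives (adjusted p up to 0.363, limma, edgeR or DESeq2), that of ACYPI001157-RA in 16 of 28 (up to 0.345), of ACYPI065920-RA in 10 of 28 (up to 0.338) and of ACYPI46674-RA in 10 of 26 (up to 0.24). In the alternatives not counted for ACYPI46674-RA it fell below the filter.

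Males and sexual females, reared under the same day length and temperature, were compared between the wingless forms to ask how the sexes of the sexual generation differ. Sexual females were 2 to 6 days old and males 2 days old, so the calls cover this difference in age range too. Wingless males had 6499 gene models higher and 5437 lower than sexual females, together 58.8% of those tested (limma, adjusted p threshold 0.05). The differences were unequal in size, with 3467 gene models at least 8-fold higher in males and 1049 at least 8-fold lower. At 32-fold the numbers were 1212 and 226. Gene models higher in males were of low overall abundance, with a median normalised count of 141.1 against 1625 for those lower in males. ACYPI47085-RA was at 17370 ± 9071 in wingless males and 3.25 ± 5.09 in sexual females (log2 fold change 12.55 ± 0.90, limma adjusted p = 5.2e-07). ACYPI44451-RA was at 18050 ± 10420 and 3.90 ± 6.21 (12.51 ± 0.91, limma adjusted p = 5.4e-07). ACYPI088619-RA stood at 751200 ± 317100 in sexual females and 1045 ± 1809 in wingless males (−15.56 ± 3.69, limma adjusted p = 0.0026), and this call was lost in 2 of 23 alternatives, without clone F1 and with edgeR, with adjusted p from 0.000599 to 0.0612. ACYPI21979-RA stood at 146400 ± 55950 and 144.7 ± 249.0 (−13.64 ± 2.47, limma adjusted p = 0.00035). Syt4 (ACYPI009209-RA) was at 6503 ± 1799 in wingless males and 7320 ± 1353 in sexual females (−0.19 ± 0.34, limma adjusted p = 0.64). In the BK11 males, 14 marker gene models of sexual females stood at a median of 1.13% of their sexual female level in the winged and 0.437% in the wingless library, which bears on the male values of both gene models named as higher in sexual females. Without clone F1 the higher calls fell to 4040, and without the 4 doubted libraries, which leaves 1 wingless male, 4638 were higher and 4209 lower.

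Sexual females were compared with wingless asexual females to ask how the reproductive modes differ in females of the same form. Sexual females had 5192 gene models higher and 4533 lower, together 47.9% of those tested (limma, adjusted p threshold 0.05). At 8-fold or more, 1504 were higher and 1881 lower, and at 32-fold or more 259 were higher and 716 lower. ACYPI088619-RA was higher in sexual females, with a log2 fold change of 18.91 ± 3.69 (limma adjusted p = 0.00077). It was represented by 1 read over the 3 wingless asexual libraries. The ratio of its mean normalised counts was 1136000, with a 95% counting interval of 204000 to 44900000 that leaves out the variation among libraries. ACYPI49694-RA stood at 1090000 ± 617200 in sexual females and 4.31 ± 0.94 in wingless asexual females (log2 fold change 17.42 ± 3.50, limma adjusted p = 0.00094). Conversely, ACYPI005591-RA stood at 106.0 ± 139.4 in sexual and 94240 ± 18020 in wingless asexual females (−11.12 ± 0.91, limma adjusted p = 7.0e-07). ACYPI010031-RA stood at 135.4 ± 160.6 and 112500 ± 25650 (−10.92 ± 1.59, limma adjusted p = 7.6e-05). The BK11 library was the highest of the sexual females for both, at 264.9 for ACYPI005591-RA and 315.1 for ACYPI010031-RA. Whether traces of asexual females raised these values was not tested. Syt4 (ACYPI009209-RA) was higher in sexual females, at 7320 ± 1353 against 1021 ± 364.6 (2.88 ± 0.34, limma adjusted p = 1.2e-05). Day length, temperature and the age range differed between these groups too, so the calls cover all of these differences together. Without the 4 doubted libraries 4666 were higher and 4268 lower.

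Both male morphs together were compared with both asexual female morphs. Males had 6592 gene models higher and 5144 lower, together 57.8% of those tested (limma, adjusted p threshold 0.05). At 8-fold or more, 2472 were higher and 803 lower. As against sexual females, gene models higher in males had low overall abundance, with a median normalised count of 125.6 against 1586 for the lower ones. ACYPI000497-RA was at 183800 ± 68910 in winged and 96920 ± 28600 in wingless males and was represented by 4 reads over the 6 asexual female libraries (log2 fold change 16.38 ± 0.65, limma adjusted p = 1.2e-09). ACYPI001912-RA was at 211300 ± 98360 in winged and 126700 ± 65900 in wingless males and near 1 in both asexual female morphs (16.25 ± 1.05, limma adjusted p = 3.0e-08). ACYPI007459-RA was at 492900 ± 66760 in wingless and 180500 ± 26390 in winged asexual females, against 108.0 ± 21.6 in wingless and 111.3 ± 41.6 in winged males (−11.43 ± 0.80, limma adjusted p = 5.6e-08). ACYPI010033-RA was at 19070 ± 5477 in wingless and 7624 ± 5158 in winged asexual females, against 11.6 ± 13.7 and 2.21 ± 1.54 in the male morphs (−11.11 ± 0.53, limma adjusted p = 2.1e-09). Syt4 (ACYPI009209-RA) was higher in males (2.10 ± 0.24, limma adjusted p = 5.8e-06). Rearing conditions differed between these groups as well, and without the 4 doubted libraries 5146 were higher and 4557 lower.

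**Figure D4:**
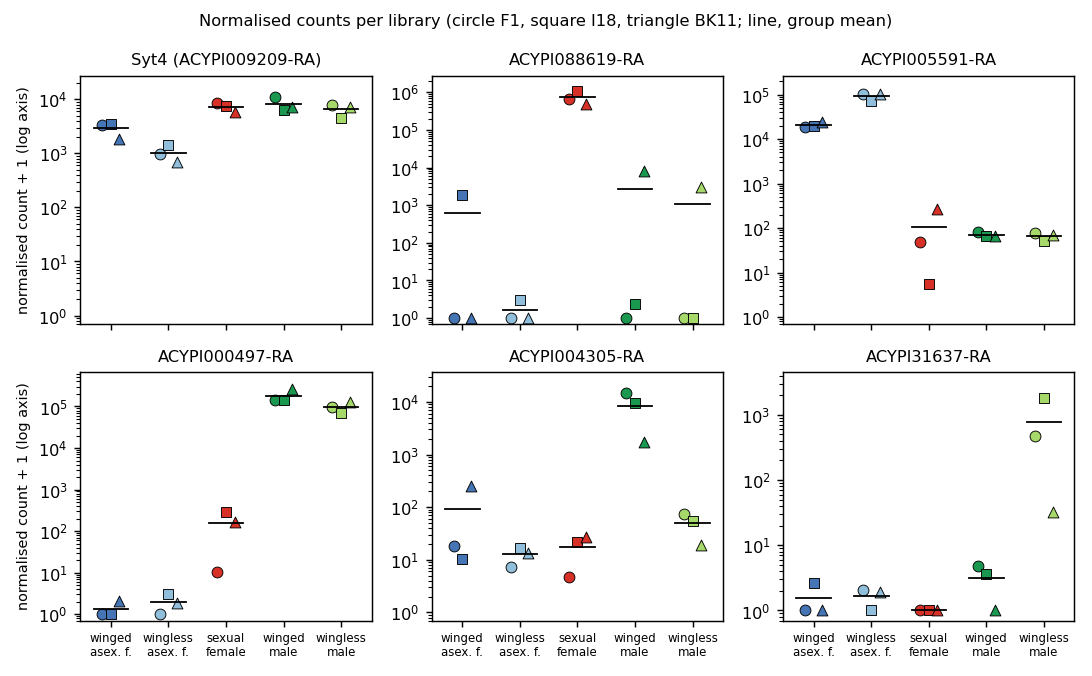
Normalised count + 1 of 6 gene models (y axes, log scale) in each library by morph (x axes), with circles for clone F1, squares for I18, triangles for BK11 and lines for the group means. Syt4 is lowest in wingless asexual females, at a mean of 1021, and ACYPI088619-RA is at a mean of 751200 in sexual females with single libraries of 3 other morphs raised above the rest of their morph.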

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

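All tests of the I18 wingless male library and of the traces of other morphs were chosen after the results were seen, and so was the test of scaling. The test of abundant genes and the counts of other splits were set before. No formal test of outlying samples within a morph was run, since each morph had 3 libraries.

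The wing effect differed between the sexes by the limma test of the difference itself in 260 gene models that were higher and 120 that were lower for males minus females. Among the named gene models this difference was 6.09 for ACYPI41054-RA, 5.95 for ACYPI065920-RA, −5.59 for ACYPI000982-RA, −6.77 for ACYPI001157-RA and −6.63 for ACYPI46674-RA on the log2 scale. Of 100 splits of the 12 libraries, 5 gave as many calls as the real 380, the real split included, and the highest other split gave 906. All of those 5 kept the real division of the asexual females into winged and wingless, as 12 of the 100 did, and the highest count among splits that did not keep it was 5. The large counts thus follow the structure of the female libraries, and since splits that keep it still hold the female wing effect, the count of splits decides nothing about chance.

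The groups of 3 against 3 allow 10 splits, too few for a share under 0.05. In each of these comparisons 1 of the 10 splits, the real one, gave as many calls. For winged against wingless asexual females the real count was 2306 and the highest other 45. It was 71 against 35 for winged against wingless males, 11936 against 0 for wingless males against sexual females, and 9725 against 0 for sexual against wingless asexual females. Of the 10 splits, 4 part the libraries of every clone as the real one does, and the highest of the other 3 was 1 for winged against wingless males and 0 for the other comparisons, while the remaining 6 place both libraries of some clones on one side. For males against asexual females, the 5 morphs and the 3 clones, 1 of 100 splits, the real one, gave as many calls. That is the lowest share 100 splits can give, so it argues against chance without excluding it. For males against asexual females and for the 5 morphs, rearing conditions go with the real grouping. The real count and the highest other were 11736 and 6548 for males against asexual females, 15134 and 4555 for the 5 morphs, and 1431 and 230 for the 3 clones. For wings in both sexes 1 of 100 splits, the real one, gave the 7 gene models and the highest other gave 0. In only 1 of the others were both lists long enough for independent lists to share 1 gene model or more, so this count decides nothing about chance.

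The I18 wingless male library stood apart from the other males, with 1087 gene models at least 4-fold above all 5 of them, against 27 to 38 in each of the others, and 1089 after thinning to the depth of the shallowest male library. These gene models held 11.5% of its normalised counts, 0.375% of those of the other males and 5.52% of those of asexual females, and 37.4% of them exceeded every female library, while their median ratio to the highest female library, the value first chosen to test a mixture and replaced after it had decided nothing, was 0.382. RNA of the sampled female morphs mixed in would bring marker genes at 1 common share, but 36.4% of 33 asexual female markers lay within 2-fold of their median share of 3.48%, and 14 sexual female markers had a median share of 0.000644% with an upper quartile of 3.74%, which argues against such a mixture as the whole source. A library of a female morph under this label is argued against by the 150 gene models restricted to the other 5 males. They stood here at a median of 1.77 times their mean in those males. The other males include winged ones, so a winged male library under this label was not tested by these gene models. Without this library, 21 gene models were higher and 8 lower in winged than in wingless males, with the filter of the full set. Of these, 26 were called in the same direction with it, which argues against a winged male library for the gene models covered. A difference of clone I18 in both male morphs was examined in the 1240 gene models at least 4-fold above the 4 males of other clones. This choice leaves the I18 winged male free. Such a difference is argued against, since 12.1% of the 1240 were 4-fold higher in the I18 winged male than in both other winged males. Their median log2 difference there was 0.26 (quartiles −0.34 and 1.27). What stays open is a mixture as part of the source, a state, tissue or stage of these I18 wingless males, or material that none of the sampled morphs represents.

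Abundant gene models of 1 morph appeared at low and nearly constant levels in a few libraries of other morphs. The 14 markers of sexual females stood at a median of 1.13% of their sexual female level in the BK11 winged male, 0.437% in the BK11 wingless male and 0.175% in the I18 winged asexual female, 16 male markers at 0.142% in the I18 and 0.119% in the BK11 sexual female, and 4 asexual female markers, too few to weigh, at 2.23% in the BK11 and 0.149% in the F1 sexual female. In the trace library with the widest spread, 78.6% of the markers lay within 2-fold of their median, in line with a small share of reads from another library or of stray individuals as a candidate source, and where these would have mixed in was not tested. Low expression of sexual female markers as a property of winged males alone, or of winged asexual females alone, is argued against. In a library of the same morph from another clone, 0% of the markers reached 10% of the trace level. The markers were chosen for a low median over the other morphs' libraries, so gene models raised in every winged library could be left out. Low expression shared by both winged morphs was therefore not decided, and low expression particular to a clone stays open. For the BK11 wingless male, low expression of these markers cannot be told apart from stray reads. In the I18 wingless male 35.7% of them reached 10% of the trace level. The same holds for male markers in sexual females, where 100% did so between I18 and BK11 and F1 stood at a median of 0.

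More gene models were lower than higher in winged than in wingless asexual females. With trimmed mean scaling 53.0% of the calls were higher, so the size-factor scaling of the deposited values may account for the direction of this split, while 88.6% of the calls themselves were shared between the scalings. A few abundant genes are argued against as holding the larger normalised total of wingless females, since the ratio of mean totals, 1.63 over all gene models, was still 1.49 without the 148 that were among the 100 most abundant in any of these libraries. A true difference in RNA content between these morphs stays open and was not tested.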

How the results depend on the processing

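Quality weights, the block without the I18 wingless male and the fit without the 4 doubted libraries were chosen after seeing the data. The counts for wingless males against sexual females, sexual against wingless asexual females, males against asexual females and the 5 morphs stayed within 1.5 times their value in every alternative, except that leaving out clone F1 gave 4040 higher for wingless males against sexual females, where leaving out a library or clone gave 4040 to 6291. Clone as a block changed no call count by over 1.5 times except winged males, 79 lower, and wings in both sexes, 6 lower. For winged against wingless asexual females, weights gave 3473 higher and 3929 lower, the fit of only the groups compared 582 higher, and DESeq2 1653 higher. Leaving out a library or clone gave 39 to 1236 higher and 132 to 1612 lower. For winged against wingless males, the higher count was 55 with pseudocount 8, 53 with weights, 22 with the block without the I18 wingless male, 1 without the 4 libraries, 3 with only the groups compared, 6 with edgeR and 122 with DESeq2. The lower count was 21 with pseudocount 0.5, 97 with pseudocount 8, 11 with the filter of 50, 7 with the block without the I18 wingless male, 0 without the 4 libraries, 0 with only the groups compared, 1 with edgeR and 501 with DESeq2. The low-value filter was applied anew to the remaining libraries, and with the filter of the full set kept, the block without the I18 wingless male gave 28 higher and 16 lower. Leaving out a library or clone gave 0 to 40 higher and 0 to 214 lower. At an unadjusted limma p under 0.05, 1558 gene models differed. For the difference between the wing effects, the higher count was 1861 with weights, 0 without the 4 libraries, 92 with edgeR and 795 with DESeq2. The lower count was 185 with trimmed mean scaling, 1633 with weights, 0 without the 4 libraries and 820 with DESeq2, and leaving out a library or clone gave 0 to 473 higher and 0 to 275 lower, with 3441 gene models at an unadjusted limma p under 0.05. Gene models called for wings in both sexes were 8 higher with trimmed mean scaling, 11 higher and 5 lower with weights, 3 and 1 with the block without the I18 wingless male, 0 and 0 without the 4 libraries, 3 and 1 with edgeR and 23 and 18 with DESeq2. Leaving out a library or clone gave 0 to 6 higher and 0 to 4 lower. Differences among clones were 887 with the filter of 50, 820 without the 4 libraries, 2522 with DESeq2 and 394 to 1514 on leaving out a library or clone. The first principal component held 38.7% with genes scaled to unit variance, 68.6% over the 1000 most variable gene models and 44.1% to 50.2% on leaving out a library. Fewer samples, fewer gene models or a lone wingless male, assumed to vary like the other groups, entered some of these fits, and beyond that the cause was not tested. DESeq2 gave no adjusted p to 312 to 4972 gene models per comparison, which were left out of its counts. Of the named gene models, no call changed direction, 113 calls under an alternative missed the threshold, most of them in the wing comparisons, and 1 was gained. Alternatives in which a named gene model was not tested are not among these. Every library held 28721904 reads or more, while in simulated data 0% of 2-fold changes were recovered for winged against wingless asexual females and 2% for males. The simulated female list held 78 calls, against 2306 in the real one, so its rate does not carry over to the real fit. The correlation of the wing effects moved by more than its spread on leaving out libraries in 6 alternatives. The planned gene list and X chromosome tests were not run.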

Other observations

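The sets below were defined after the data were seen. Gene models that parted morphs without overlap were counted by requiring every library of a set to have a normalised count of at least 100 and at least 20 times the highest library outside it. By this measure 180 gene models belonged to the 6 male libraries, and they held 6.20% of the male normalised counts on average, from 4.51% to 8.37% per library. Another 24 belonged to the 6 asexual female libraries, with 1.13% to 2.00% of their counts, and 14 to the 3 sexual female libraries, with 1.94% to 4.54%. The rule turns on the highest library outside a set, so a doubted library can remove a gene model. ACYPI010031-RA missed the asexual female set through the I18 wingless male, at 2300. Its next outside library stood at 660.3 and its lowest asexual female at 21298. ACYPI49694-RA missed the sexual female set through the same library, at 33845, with 13050 next and 380007 in the lowest sexual female. Such losses were not counted, so 180, 24 and 14 cannot be ranked. No gene model belonged to winged males alone, wingless males alone, winged asexual females alone, wingless asexual females alone or the 6 winged libraries of both sexes. Of the 5004 sets of 6 libraries other than the males, 3 held any gene model, the asexual females with 24 the most, and of the 454 sets of 3 other than the sexual females 1 did, with 3.

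Sexual females and males were also compared with asexual females over separate libraries, sexual against wingless asexual females and winged males against winged asexual females. Of the 5192 gene models higher in sexual females and the 4430 higher in winged males, 1294 were called in both, against 1133 for independent lists of these sizes (limma, adjusted p threshold 0.05). Of the 4533 and 3890 lower ones, 1456 were shared, against 868.6 for independent lists. Both comparisons came from the same fit and shared its estimate of spread, so some excess over independent lists can arise without shared effects. A further 1841 gene models were called in both with opposite directions, against 1984 for independent lists, and both sexual morphs were reared at the same day length and temperature, unlike the asexual females.

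Clones differed in an on and off manner in a small number of gene models. In 45, all 5 libraries of 1 clone had a normalised count of at least 100 and at least 20 times the highest library of another clone. Among all 1296 ways to relabel the clones within morphs, 1 gave as many, the real one, and the highest other gave 24. F1 alone was low for 5 of these and alone high for 6, BK11 alone low for 3, and I18 alone high for 2.

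The BK11 winged male had 368 gene models at least 4-fold below all other males, against 57 to 102 in the other male libraries. The F1 sexual female had 2104 gene models at 0, the most of any library, and the I18 wingless male 192, the fewest.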
